A study of Glycine max with 4 samples.

How the data were processed

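The series measured total RNA of whole soybean roots in 4 groups of 3 biological replicates on 14 two-colour arrays. Per the labels, RNA was isolated with RNeasy columns and labelled with Agilent's Quick Amp kit, Cy5 marked the sample and Cy3 a pool of control roots. All arrays used the same dye orientation, so a dye effect that differs between genes is common to all groups and drops out of the differences between them. Group and replicate were taken from the labels and the array names. Replicate 3 of the control and of the mycorrhizal group had 2 technical arrays.

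Per the file headers, the arrays were scanned with an Agilent G2505B scanner and quantified with Feature Extraction 9.1.3.1, protocol GE2-v5_91_0806. The deposited array files give the mean spot signal and the median local background of each channel as intensity, without normalization. They also give processed signals as intensity, after background subtraction with spatial detrending and a linear and lowess dye normalization within the array by that software. The deposited log ratio is the log10 of processed Cy5 over processed Cy3. Flags per spot were used as deposited. The authors' value table holds a score per group, a signed linear fold change that is at or above 1 or at or below -1. Its centring and its reference are not stated. Per the submitters' processing notes limma was used, with no version given. The log2 of that score followed this work's group means across 42747 probes with r of 0.87 for control, 0.88 for pathogen, 0.78 for mycorrhizal and 0.82 for mycorrhizal pathogen roots. It was used only for that check and for the named genes, because it has a single value per group.

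The values used here started from the mean spot signals. In R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), the background was corrected with normexp and an offset of 50, and log ratios were normalized by loess within each array. Control spots (1417 of 44165) and spots marked as non-uniform or population outliers had no weight. No scaling between arrays was applied, each probe had 1 spot per array, and technical arrays of 1 replicate were averaged. Over the 14 arrays the median Cy5 signal above background was 69.1 to 475.6 and that of Cy3 58 to 205.9. The number of arrays limits the precision. Log ratios of the technical arrays correlated across probes at r = 0.20 for control replicate 3, where both channels hold control roots, and at 0.92 for mycorrhizal replicate 3. The lowest correlation between any 2 arrays was 0.015, and -0.38 with Agilent's log ratios, between control and pathogen replicate 1. The labels state the same dyes for every array, and no array was turned.

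Probes were kept if well above background in Cy5 on every array of at least 1 group. That left 34235 of 42748, of which 34234 could be tested, and dim probes were left out because their ratios are set by the background. Missing values numbered 248 in 208 probes. All 4 groups were fitted together with lmFit and eBayes (8 residual degrees of freedom). The comparisons were the pathogen effect without and with mycorrhiza, the mycorrhizal effect without and with the pathogen, the difference between the 2 pathogen effects, and both average effects. P-values were adjusted by Benjamini and Hochberg within each comparison, and 0.05 was the threshold. They measure spread between these pools of plantlets together with that of arrays and slides, since most replicates had a single array. A common growth batch would be shared by the pools.

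Gene texts came from the array files: 24797 probes had text that names a gene, 3802 of them from similarity notes, and 17951 had only a library or clone. The reference table of soybean genes matched 0 probes by identifier, and no name was taken from it. Before the data were examined, 27 gene lists were fixed as text patterns, and camera with a preset correlation of 0.01 compared each with all other genes. Camera with an estimated correlation and fry were run beside it. The named genes follow a rule fixed at the same time. For each comparison these are the 6 largest rises and the 6 largest falls among informative probes past the threshold without overlap between replicates, with 1 probe per name. The rule adds up to 2 members with the smallest p of each list that has a member past the threshold. The no-overlap condition was not applied to the interaction. The rule also names the 5 smallest p where fewer than 5 probes pass, which occurred in no comparison. The report gives part of these genes in full, and the values whose sign turned with Agilent's signals are in the closing section. A fold is a lower bound ("at least") where 1 group was near background.

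The lists were phenylpropanoid and lignin, isoflavonoid and flavonoid, pathogenesis-related proteins, protease inhibitors, jasmonate, ethylene, salicylate signalling, mycorrhiza markers, common symbiosis and strigolactone, class III peroxidases and oxidative burst, glutathione S-transferases, antioxidant enzymes, WRKY, MYB and NAC factors, disease resistance and receptor-like kinases, cell wall remodelling, heat shock proteins, photosynthesis, nodulins, seed proteins, ribosomal proteins, histones and cell cycle, auxin, abscisic acid and drought, phosphate starvation, and nitrate and water transport.

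The fit and the list test were tried on simulated replicate log ratios of 34027 probes, 100 of them changed per size. Background correction, loess and the filter were not part of this trial. A log2 change of 1 was recovered for 56 probes in the pathogen comparison, 61 in mycorrhizal roots, 65 and 63 for mycorrhiza without and with the pathogen, 23 for the interaction, and 82 and 78 for the averages. A change of 2 was recovered for 93, 95, 92, 97, 80, 97 and 98 probes in the same order. Between 3 and 13 false calls were made per comparison, among 33781 to 33783 unchanged probes. A list shifted by 0.5 was always called, and 0 of the 26 others were. The noise was drawn separately for each probe, without correlation between genes or a slide structure. The trial therefore cannot show how often lists of correlated genes are called by chance.

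Alternatives planned in advance were Agilent's processed signals and log ratios, no background subtraction, median centring in place of loess, Aquantile or scale normalization between arrays, Cy5 alone, no filter or a filter on both channels, either technical array alone, array weights, limma's trend and robust options, a fold minimum of 2, only the groups compared, replicate number or slide as a block, and leaving out each replicate. The replicate block gave 1926 probes for the pathogen and 0 for the interaction (2391 and 6 without it). Added after the arrays were seen were a refitted background, that refit without mycorrhizal replicate 3, a fit without the dim slide, and a fit that kept outlier spots. The refit was added because 6 spots of pathogen replicate 3 and 15 of mycorrhizal pathogen replicate 2 lay more than 100 below background. They pulled the normexp background mean to -190.7 and -386.5, against -15.5 to -1.9 on the other arrays, and with spots on uneven background left out these means were 0.2 and -3.4. The planned fit was kept as the main one, and counts from the refit are given beside it.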

Results

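RNA from whole soybean (Glycine max) roots was measured on 14 two-colour oligonucleotide arrays. The plantlets, grown in vitro, fell into 4 groups. Control roots received no fungus. A second group received the pathogen Macrophomina phaseolina, a soil fungus that rots soybean roots. A further group was first colonized by an arbuscular mycorrhizal fungus, which lives inside root cells and trades minerals for sugar. The last group was first colonized and then received the pathogen. Each group held 3 biological replicates, each a pool of roots from 2 plantlets. Replicate 3 of the control group and of the mycorrhizal group was measured on 2 arrays, which were averaged. On every array Cy5 carried the sample and Cy3 a pool of control roots, so each value is a log2 ratio to that reference.

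Median Cy5 brightness above the local background ranged from 69.1 to 475.6 between arrays. The 3 arrays of slide 1 (replicate 1 of the control, pathogen and mycorrhizal pathogen groups) were the dimmest, at 69.1, 71 and 92.8, and 70.7% to 75.7% of their spots lay well above background, against 79% to 85.8% elsewhere. No spot was saturated (0 in either channel). The number of arrays limits the precision. Of 42748 probes, 34234 were tested, and 16202 of those had a text that says what the gene is. Gene names below are those of the array files, with the sequence identifier in parentheses. Many of them were taken from similar genes of other species. Of the variance between the 12 replicates, 44.5% lay along a first component that put the controls at -52.66 to -45.46 and the pathogen group at 32.86 to 59.26. Mycorrhizal replicate 3 stood at 1.07 on it, and the other mycorrhizal replicates at -46.63 and -44.63. Mycorrhizal pathogen replicate 2 stood at 7.18, and the others of its group at 54.36 and 35.48. These positions come from the planned background fit, which was misfitted on that replicate and on pathogen replicate 3. On a scale with the control mean at 0 and the pathogen mean at 1, mycorrhizal pathogen replicate 2 had 0.653 in the planned fit. With the refitted background it had 0.865, so its place on the component does not show a weaker response of that pool.

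The first comparison asks which genes the pathogen changed in roots without mycorrhiza. The probe for 12-oxophytodienoate reductase (BU549803) rose by 6.96 ± 0.52 on the log2 scale (SE, n = 3 per group), 124-fold, with an adjusted p of 3.93e-05. Of the 8 other probes with that name, 3 also rose and 1 had the opposite sign without passing. Glutathione S-transferases GST 7 (BW666684) and GST 10 (BW677943) rose by 6.01 ± 0.66 and 5.67 ± 0.64, and GST 12 (BI971101) by 4.49 ± 0.18, 22.4-fold, with an adjusted p of 2.23e-07. Cytochrome P450 84A1 (BE022898) rose by 6.13 ± 1.07 and CPRD2 (CF805949), named for a drought-induced cowpea gene, by 5.99 ± 0.54. A probe named 60S ribosomal protein L10 (CX709006) rose 86.3-fold, by 6.43 ± 0.43. Of its 4 namesakes none passed and 2 had the opposite sign.

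The list shifts below are calls by camera with its preset correlation between genes. With an estimated correlation none of the 15 lists called for this comparison passed (0 by camera, smallest adjusted p 0.269), whereas fry called 7. Of 46 glutathione S-transferase probes, 21 rose, 0 fell and 25 did not pass, and adjusted over the list alone 23 rose and 1 fell. The median of that list was 0.54 (camera adjusted p 5.44e-09). In the isoflavonoid and flavonoid list of 68 probes, 21 rose and 3 fell, with 29 and 3 adjusted over the list alone and a median of 0.35 (adjusted p 3.42e-08). Cytochrome P450 CYP93A1 (BU578331), an enzyme of soybean phytoalexin synthesis, rose by 4.50 ± 0.72, and the reductase of deoxychalcone synthesis (CX548207) by 2.80 ± 0.43. In the phenylpropanoid and lignin list of 75 probes, 15 rose and 1 fell (21 and 3 adjusted over the list alone). The median of that list was 0.27 (adjusted p 3.66e-05). Phenylalanine ammonia-lyase (BW684753) rose by 2.44 ± 0.37, and its 4 other probes rose too. A dirigent-type protein (BU083075) rose by 1.5 ± 0.20. The pathogenesis-related list as a whole did not shift (median 0.00091, adjusted p 0.577), but 11 of its 85 probes rose and 2 fell (12 and 6 adjusted over the list alone). Class I chitinase Chia1 (CO981370) rose by 3.60 ± 0.41 and beta-1,3-glucanase (BU549819) by 2.77 ± 0.25. Of 26 protease inhibitor probes 3 rose and 0 fell (4 and 0 adjusted over the list alone; median 0.25, adjusted p 0.0148), among them a cysteine proteinase inhibitor (BW673849) at 3.00 ± 0.43.

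Hormone and regulator genes moved in both directions. In the abscisic acid and drought list of 64 probes, 12 rose and 0 fell, with 16 and 1 adjusted over the list alone (median 0.13, adjusted p 0.00213). That call ended without slide 1, where the median was 0.03 (adjusted p 0.0681), with array weights (0.03, 0.0785) and with Agilent's log ratios (0.76, 0.0517), and over all alternatives ran from 2.46e-05 to 0.0785. Of the pathogen replicates the first had a list median of 0.14 and the others 0.02 and -0.02. The abscisic acid synthesis gene NCED1 (BW672813) rose by 3.32 ± 0.36, and an ABA-responsive protein (BW664075) by 2.96 ± 0.11. Of 46 NAC probes 9 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.20, adjusted p 0.00059, but 0.342 and 0.473 with Agilent's processed signals and log ratios), with the NAM family protein CO979738 at 3.62 ± 0.30. Of 54 WRKY probes 6 rose and 1 fell, and the same numbers passed adjusted over the list alone (median 0.08, adjusted p 0.0294). WRKY-b (CX704835) rose by 3.32 ± 0.51. The jasmonate list did not shift (adjusted p 0.561), with 9 rises and 6 falls among 75 probes, and 16 and 11 adjusted over the list alone. A lipoxygenase (CO978879) rose by 2.32 ± 0.34. In the auxin list of 121 probes 5 rose and 7 fell (6 and 11 adjusted over the list alone), and the median was -0.11 (adjusted p 0.00353). With Agilent's log ratios it was 0.03, below the 0.30 of all probes, and did not pass. The auxin-responsive GH3 probe BU547810 rose against the median of -0.11, by 2.05 ± 0.27. Among 320 heat shock and chaperone probes, 30 rose and 3 fell (31 and 4 adjusted over the list alone; median 0.07, adjusted p 0.016). With median centring the median was -0.02 against -0.08 over all probes, and the call held (adjusted p 0.048). Hsp23.9 (CD395434) rose by 2.73 ± 0.24, while the copper chaperone BM522567, at 1.82, is in the list by name alone.

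Among single genes the high-affinity nitrate transporter NRT2 (BW661840) fell by 3.90 ± 0.49, 14.9-fold, with an adjusted p of 0.00115. CPRD49 (BW682525) fell by 3.79 ± 0.57, polygalacturonase PG2 (CO980415) by 3.59 ± 0.42, and major latex protein 15 (CA851827) by 3.57 ± 0.67. The cysteine proteinases CysP1 (BE660770) and CysP2 (BW679860) fell by 2.89 ± 0.48 and 2.88 ± 0.44. Each of these 6 falls kept a negative value with Agilent's log ratios but missed the threshold there. The list calls here, as above, were lost with an estimated correlation. In the nitrate and water transport list of 59 probes, 2 rose and 5 fell, and the same numbers passed adjusted over the list alone (median -0.30, adjusted p 0.00161, but -0.17 and 0.256 with Agilent's processed signals and -0.24 and 0.128 with its log ratios). In the cell wall list of 217 probes, 7 rose and 14 fell, with 7 and 15 adjusted over the list alone (median -0.20, adjusted p 0.000154). Of 196 histone and cell cycle probes, 2 rose and 12 fell, and the same numbers passed adjusted over the list alone (median -0.12, adjusted p 0.000517). With Agilent's processed signals and log ratios the median was 0.09 and 0.03, below the 0.20 and 0.30 of all probes, and did not pass. Of 57 phosphate starvation probes 2 rose and 7 fell (3 and 11 adjusted over the list alone; median -0.26, adjusted p 0.000338, but 0.26 and 0.01 with the same 2 settings, where all probes had 0.20 and 0.30). Photosynthesis genes, chosen to show shoot tissue, had a median of -0.26 (adjusted p 5.44e-09), with 0 rises and 5 falls among 185 probes and 0 adjusted over the list alone. Ribosomal protein genes had a median of 0.10 (adjusted p 0.0186), with 8 rises and 3 falls among 497 probes, and 3 and 1 adjusted over the list alone. The median was -0.08 with median centring and -0.005 with Cy5 alone, against -0.08 and -0.05 over all probes, and neither passed.

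The other 10 lists did not shift. Their camera adjusted p were 0.588 for ethylene and for MYB factors, 0.571 for common symbiosis, 0.561 for nodulins and 0.479 for class III peroxidases. It was 0.963 for salicylate signalling, mycorrhiza markers, antioxidant enzymes, resistance genes and receptor-like kinases, and seed proteins. Of 138 resistance and receptor-like kinase probes, 15 rose and 2 fell (19 and 6 adjusted over the list alone), although the median of that list was -0.06 against a mean of 0.17. Of 105 mycorrhiza marker probes, 10 rose and 4 fell, with 12 and 7 adjusted over the list alone, a median of -0.03 and a mean of 0.01. The ethylene median was -0.09 and its mean 0.07, with 6 rises and 4 falls (7 and 7 adjusted over the list alone).

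In limma, 2391 probes passed for the pathogen without mycorrhiza, 1553 of them higher and 838 lower (736 and 1069 with median centring). Of these, 2390 showed no overlap between the 3 and 3 replicates. Chance gives this to 10% of unselected probes, but these were called on the same values, which nearly fixes the outcome. On slides 1, 2 and 3, which each held both groups, the list medians kept their sign, except for abscisic acid (-0.03 on slide 3) and ribosomal proteins (-0.02 on slide 1). The rises had medians of 1.38, 1.27 and 1.14 there, but as called probes do not overlap between replicates, their sign on a slide is close to fixed and tests nothing about the slide. With slide as a block 3120 probes passed, and the WRKY and ribosomal lists missed the threshold (adjusted p 0.0547 and 0.108; over all alternatives 0.00721 to 0.566 and 3.03e-06 to 0.446). The count was 1165, 1295 and 1016 without control replicates 1, 2 and 3, and 1278 and 1138 without pathogen replicates 1 and 2. The protease inhibitor list ended without control replicate 2 (0.0642) or pathogen replicate 1 (0.0627), WRKY without control replicate 1 (0.155) or pathogen replicate 3 (0.0638), heat shock without pathogen replicate 2 (0.0588), and ribosomal proteins without control replicate 2 (0.246) or pathogen replicate 2 (0.364). Agilent's processed signals and log ratios also ended the calls of WRKY factors (0.492 and 0.566), auxin (0.156 and 0.159), heat shock (0.237 and 0.159), histones (0.341 and 0.164) and phosphate starvation (0.762 and 0.435), and the log ratios those of protease inhibitors and ribosomal proteins (0.074 each). No alternative ended the calls of glutathione S-transferases, isoflavonoids, phenylpropanoids, cell wall and photosynthesis with the preset correlation, whereas 9 ended that of WRKY factors, 7 that of ribosomal proteins and 6 that of protease inhibitors. Agilent's processed signals left 271 probes, and the background model refitted without spots on uneven background left 3600.

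**Figure D1:**
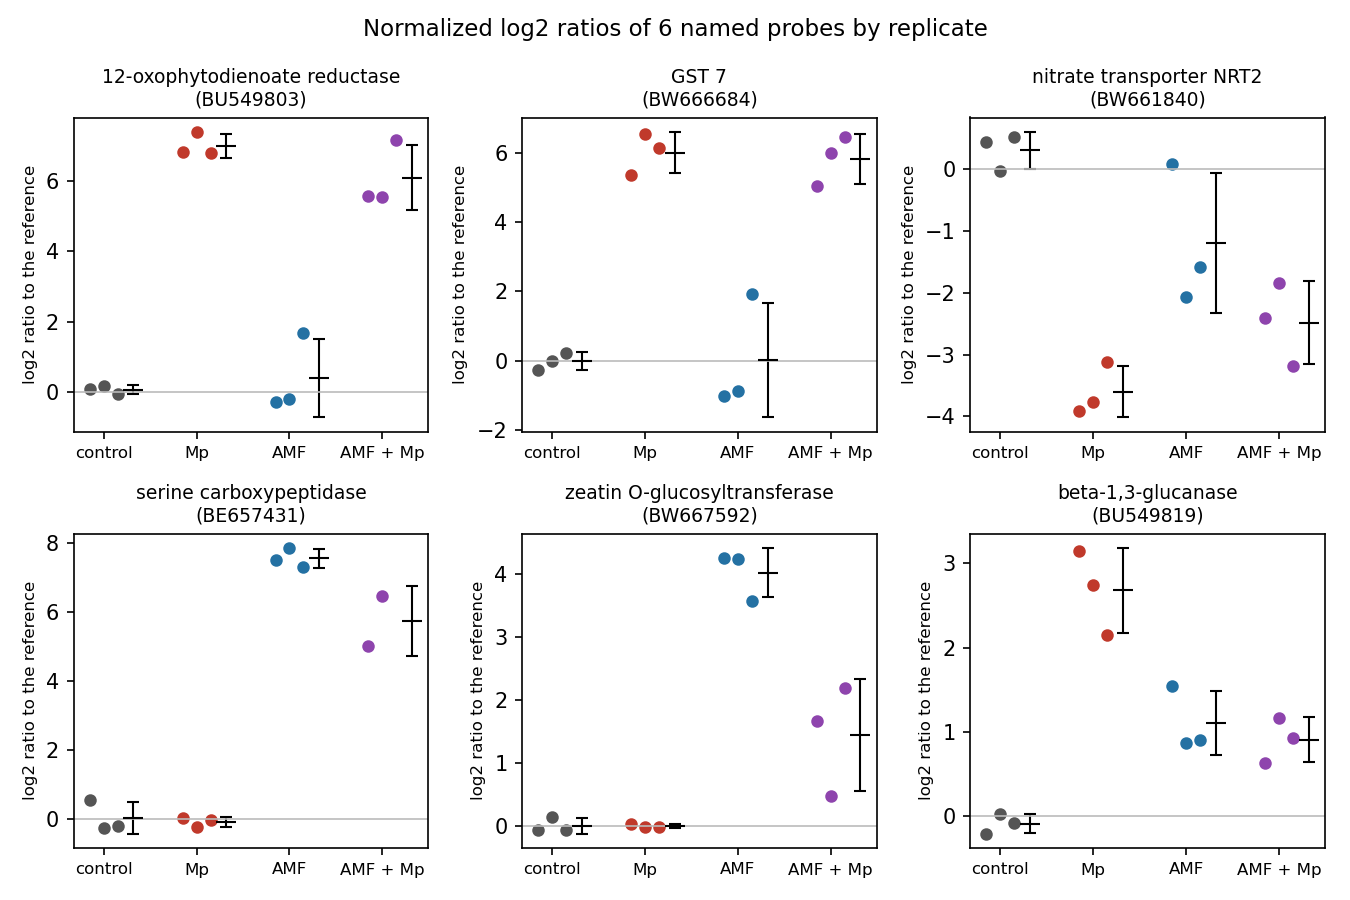
Log2 ratio to the pooled control reference (y axis) for 6 genes in the 4 groups. Points are biological replicates and the black bar is the mean with the SD (n = 3, or 2 where a value is missing). 12-oxophytodienoate reductase and GST 7 were higher in both pathogen groups, NRT2 was lower in the pathogen group, and the serine carboxypeptidase (BE657431) and zeatin O-glucosyltransferase were higher in mycorrhizal roots.

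The next comparison asks the same of mycorrhizal roots, where the pathogen raised many of the same genes. GST 7 rose by 5.80 ± 0.66 (n = 3 per group), 12-oxophytodienoate reductase by 5.72 ± 0.52, 52.7-fold with an adjusted p of 0.000319, and GST 12 by 4.99 ± 0.18, 31.7-fold with an adjusted p of 1.77e-07. The L10-named probe (CX709006) rose by 6.02 ± 0.43, CPRD2 by 5.06 ± 0.54 and GST 10 by 4.91 ± 0.64. NCED1 rose by 2.79 ± 0.36, the ABA-responsive protein by 2.44 ± 0.11, the NAM family protein by 2.66 and Hsp23.9 by 2.44 ± 0.24. The largest falls were mostly of genes that were high in mycorrhizal roots. Zeatin O-glucosyltransferase ZOG1 (BW667592), which stores the hormone cytokinin, fell by 2.58 ± 0.35, a cucumisin-type protease (BI971063) by 2.50 ± 0.39, and a reversibly glycosylated polypeptide (BW655745) by 2.44 ± 0.25. Carbonic anhydrase (BW660123) fell by 2.42 ± 0.22 and germin-like protein 1 (CO983251) by 2.29 ± 0.26. With the refitted background these 5 falls were -1.87, -1.66, -1.94, -1.95 and -1.80, and each still passed. The cucumisin fall did not pass without mycorrhizal replicate 1 (adjusted p 0.0665; over all alternatives 0.00034 to 1). CPRD49 fell by 2.87 ± 0.57 (adjusted p 0.0364), but failed in 17 alternatives (0.0124 to 1). Among these were control replicates 1, 2 and 3 left out (0.0536, 0.0612 and 0.0659), pathogen replicate 2 (0.0583), mycorrhizal replicates 1 and 2 (0.168 and 0.135) and mycorrhizal pathogen replicate 1 (0.056).

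By camera with the preset correlation 11 lists passed in mycorrhizal roots, but with an estimated correlation none did (0, smallest adjusted p 0.549), and fry called 1. Glutathione S-transferases had 8 rises and 1 fall among 46 probes, 17 and 2 adjusted over the list alone, and a median of 0.40 (adjusted p 2.1e-10). Of 64 abscisic acid probes 4 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.04, adjusted p 0.00971). With median centring the median was -0.02 against -0.10 over all probes, and with Cy5 alone -0.03 against -0.02. The call held in both (adjusted p 0.0247 and 0.0243). Heat shock genes had 7 rises and 0 falls (8 and 0 adjusted over the list alone; median 0.04, adjusted p 0.0273). With median centring they had a median of -0.05 against -0.10 over all probes, and did not pass (adjusted p 0.0694). NAC factors had 1 rise and a median of 0.09 (adjusted p 0.0103), and ribosomal proteins 1 rise, 1 fall and a median of 0.12 (adjusted p 9.76e-05). The isoflavonoid list had a median of 0.10 (adjusted p 0.0296), with 0 rises and 1 fall. Photosynthesis (median -0.32, adjusted p 1.77e-12), phosphate starvation (-0.26, adjusted p 0.000716) and cell wall genes (-0.22, adjusted p 0.000149) shifted down without a single probe past the threshold (0 in limma). Histones (-0.09, adjusted p 0.0234) and pathogenesis-related genes (-0.16, adjusted p 0.0322) shifted down with 1 fall each. The phenylpropanoid list, raised in roots without mycorrhiza, had a median of -0.05 here (adjusted p 0.896). The remaining 15 lists did not pass either. They include auxin (adjusted p 0.236, 1 rise and 3 falls), jasmonate (adjusted p 0.236, 2 and 2) and nitrate and water transport (adjusted p 0.997).

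In total 397 probes passed in mycorrhizal roots (4173 at an unadjusted p under 0.05), 244 higher and 153 lower (96 and 196 with median centring, 7 and 37 with scaling between arrays). None of them overlapped between replicates, which the call nearly fixes. On slides 2 and 5, which held both groups, the rises had medians of 1.61 and 1.38 (their sign is close to fixed by the call), and the list medians of isoflavonoids, NAC factors and histones turned on slide 5 (-0.06, -0.11 and 0.01) and that of heat shock on slide 2 (-0.03). The slide block gave 254 probes, and ended the isoflavonoid and histone calls (adjusted p 0.0701 and 0.0513; over all alternatives 1.07e-06 to 0.297 and 0.000843 to 0.299). The count was 165, 166 and 1010 without mycorrhizal replicates 1, 2 and 3, and 213 without mycorrhizal pathogen replicate 1. Of the 11 list calls only those of glutathione S-transferases, photosynthesis and phosphate starvation held without each replicate in turn. Without mycorrhizal replicate 1 the isoflavonoid and ribosomal calls ended (0.12 each), without replicate 2 isoflavonoids (0.297), NAC factors (0.0846) and histones (0.299), and without replicate 3 pathogenesis-related (0.336) and heat shock genes (0.145). Without mycorrhizal pathogen replicate 1 the calls of pathogenesis-related genes (0.317), cell wall (0.0762), heat shock (0.317) and ribosomal proteins (0.674) ended, without replicate 2 isoflavonoids (0.182) and abscisic acid (0.0831), and without replicate 3 isoflavonoids (0.19), pathogenesis-related genes (0.063) and histones (0.0677). Calls began for protease inhibitors without mycorrhizal replicate 3 (0.0188), for jasmonate (0.0127), ethylene (0.00907), peroxidases (0.00639) and auxin (0.0375) without replicate 2, and for peroxidases without mycorrhizal pathogen replicate 2 (0.00414). The pathogenesis-related call ended in 14 alternatives, among them the refitted background (0.0601), no background subtraction (0.0645), median centring (0.0765), scaling between arrays (0.135) and no filter (0.143), and ran from 0.00583 to 0.409. The heat shock call ended in 9 and ran from 0.00639 to 0.330. Agilent's processed signals and log ratios ended the calls of pathogenesis-related (0.13 and 0.156), heat shock (0.0753 and 0.0621) and histone genes (0.0887 and 0.0621). The refitted background gave 751 probes and Agilent's processed signals 33.

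The responses to the pathogen with and without mycorrhiza share no sample and can be set side by side. They do share each probe's estimate of spread and some slides. The counts given for independent calls are therefore only a rough reference. Of the 244 rises in mycorrhizal roots, 238 were among the 1553 rises in the other roots, against 11.1 if the calls were independent. Of the 153 falls 45 were shared, against 3.75. Across probes, which are not independent replicates, the log2 changes had a Pearson r of 0.72 and a Spearman rho of 0.51. Of the probes that rose without mycorrhiza 94.0% had the same sign in mycorrhizal roots, where their median was 0.60 against 1.25. Of those that fell 93.9% had the same sign, with medians of -0.40 and -0.81. The probes were selected in roots without mycorrhiza, which favours a larger median there. Mycorrhizal replicate 3, at 0.482 of the pathogen response, also lowers the change measured in mycorrhizal roots. So can the misfitted background of mycorrhizal pathogen replicate 2, whose share of that response was 0.653 in the planned fit and 0.865 with the refit. For pathogen replicate 3, misfitted too, these shares were 0.923 and 0.982. The medians above are from the planned fit.

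Mycorrhiza without the pathogen is the subject of the next comparison. A serine carboxypeptidase (BE657431) rose by 7.51 ± 0.34 (n = 3 per group), 183-fold, with an adjusted p of 7.59e-06. The cucumisin-type protease rose by 4.86 ± 0.39, at least 25.8-fold, and ZOG1 by 4.02 ± 0.35, at least 14.4-fold, since both were near background in control roots. A DNA-binding protein (CX711554) rose by 4.03 ± 0.38, the GH3 probe BU547810 by 3.66 ± 0.27, the reversibly glycosylated polypeptide by 3.65 ± 0.25 and germin-like protein 1 by 3.58 ± 0.26. A second serine carboxypeptidase probe (CO985404) rose by 3.27 ± 0.18, 9.68-fold. Of 36 other probes with that name 3 rose too and 16 had the opposite sign. An auxin response element-like sequence (BU547804) rose by 2.10 ± 0.18. These rises held without each replicate in turn. Falls were fewer and smaller. GTP cyclohydrolase I (BW655925) fell by 1.21 ± 0.22 (adjusted p 0.0332) and vacuolar ATPase subunit E (BW682479) by 0.64 ± 0.10 (adjusted p 0.0117). The first fall was lost without control replicate 1, 2 or 3 (0.166, 0.0524 and 0.15), mycorrhizal replicate 1 or 2 (0.155 and 0.149) or mycorrhizal pathogen replicate 3 (0.0522), and ran from 0.00908 to 0.473 over all alternatives. The other was lost without control replicate 1 or 2 (0.0651 and 0.0696) or mycorrhizal replicate 1 (0.0579), and ran from 0.00195 to 0.52.

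Of 105 mycorrhiza marker probes 6 rose and 0 fell, with 6 and 1 adjusted over the list alone, and the list's median of 0.04 did not differ from that of other genes (adjusted p 0.17). The 2 named members that rose are serine carboxypeptidases, a family that also acts outside mycorrhiza. The 7 list calls that follow are by camera with the preset correlation, and none passed with an estimated correlation (0 by camera, smallest adjusted p 0.704) or in fry (0). The common symbiosis and strigolactone list had higher values (median 0.27, adjusted p 9.24e-06), with 0 past the threshold in limma but 9 rises and 1 fall adjusted over the list alone. Its text pattern takes in any probe named GRAS, carotenoid cleavage dioxygenase or calcium/calmodulin-dependent protein kinase. It does not stand for the symbiosis pathway alone. Phenylpropanoid genes (median 0.20, adjusted p 0.00481; 2 rises adjusted over the list alone), photosynthesis genes (0.14, adjusted p 9.24e-06) and ribosomal protein genes (0.11, adjusted p 0.0022, 1 rise) were higher too, but photosynthesis did not pass with Agilent's processed signals (0.441) or log ratios (0.493), ribosomal proteins with median centring (median 0.03, 0.461) or Cy5 alone (0.04, 0.105), or phenylpropanoids with median centring (0.0507). Class III peroxidases (-0.10, adjusted p 0.00899, 1 rise and 1 fall), cell wall genes (-0.12, adjusted p 0.00308, 1 rise) and nitrate and water transport (-0.18, adjusted p 0.00435; 2 falls adjusted over the list alone) were lower. They had medians of 0.10, 0.07 and 0.30 with Agilent's processed signals and 0.06, 0.21 and 0.26 with its log ratios. All probes had 0.17 and 0.27 in these settings, and none of the 3 lists passed there (0.441 to 0.607). The glutathione S-transferase list had 2 rises and did not shift (adjusted p 0.721). Neither did the pathogenesis-related list, with 1 rise, or 5 adjusted over the list alone.

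In limma, 181 probes passed for mycorrhiza without the pathogen (3811 at an unadjusted p under 0.05), 165 higher and 16 lower (1064 and 1003 with array weights, 226 and 85 with the refitted background, 230 and 87 without mycorrhizal pathogen replicate 2). None of them had overlapping replicates, which the call nearly fixes. The rises had medians of 1.34, 1.60 and 1.21 on slides 2, 3 and 4, with the sign again close to fixed by the call. On single slides the phenylpropanoid median turned (-0.17 on slide 3), as did that of photosynthesis (-0.04 on slide 4). The slide block gave 208 probes, ended the phenylpropanoid call (adjusted p 0.0719; over all alternatives 3.6e-05 to 0.197) and added the mycorrhiza markers (0.000465). The count was 91, 93 and 82 without control replicates 1, 2 and 3, 113, 102 and 292 without mycorrhizal replicates 1, 2 and 3, and 317 without mycorrhizal pathogen replicate 2. Without mycorrhizal replicate 3 the phenylpropanoid (0.197) and cell wall (0.574) calls ended, and the mycorrhiza marker list passed upward (0.05, adjusted p 0.0327) and the glutathione S-transferase list downward (-0.13, 0.0327). Without mycorrhizal replicate 2 the calls of peroxidases (0.265), ribosomal proteins (0.519) and nitrate and water transport (0.0845) ended, and without control replicate 2 that of ribosomal proteins (0.107). Without mycorrhizal replicate 1 glutathione S-transferases passed upward (0.12, 0.0488), the opposite of the above, as did isoflavonoids (0.0303), and jasmonate (0.0205) and phosphate starvation (0.0113) passed downward. Without replicate 2 isoflavonoids and WRKY factors (0.00219 each) and NAC factors (0.0328) passed upward and histones (0.0095) downward, and without control replicate 1 jasmonate passed downward (0.0324). The refitted background gave 311 probes and Agilent's processed signals 35.

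Mycorrhiza in the presence of the pathogen was compared last among the pairs of groups. The serine carboxypeptidase BE657431 was again highest, with a rise of 5.82 ± 0.38, 56.5-fold (adjusted p 0.000305), measured in 2 of the 3 mycorrhizal pathogen pools. The second probe, CO985404, rose by 1.91 ± 0.18 (adjusted p 0.00337), and the DNA-binding protein CX711554 by 2.96 ± 0.38 (adjusted p 0.0396). The last of these was lost without control replicate 1 or 3 (0.0886 and 0.0549), pathogen replicate 2 or 3 (0.31 and 0.0797), mycorrhizal replicate 1 (0.055) or any mycorrhizal pathogen replicate (0.11, 0.0564 and 0.0668), with a range of 0.00836 to 1 over all alternatives. Of its 11 namesakes 8 had the opposite sign, here and with mycorrhiza alone. All 7 probes that passed were higher and also rose with mycorrhiza alone (0.0337 of 7 if independent, a rough reference since both comparisons share each probe's estimate of spread). They did not overlap between replicates, which the call nearly fixes. The 165 probes raised by mycorrhiza alone had the same sign here in 85.5% of cases, with medians of 0.35 here and 1.39 there. They were selected with mycorrhiza alone, which favours a larger median there. The misfitted background of mycorrhizal pathogen replicate 2 can also lower the median here. Over the 7 probes its median log2 ratio was 1.87 in the planned fit and 2.56 with the refit. Across all probes, r was 0.27 and rho 0.21.

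By camera with the preset correlation 12 lists passed, and none with an estimated correlation (0, smallest adjusted p 0.399) or in fry (0). Jasmonate (median -0.29, adjusted p 3.53e-07), isoflavonoid (-0.33, adjusted p 1.07e-05), class III peroxidase (-0.27, adjusted p 7.77e-05) and phenylpropanoid genes (-0.22, adjusted p 0.000199) were lower in mycorrhizal than in other roots under the pathogen. So were cell wall (-0.12, adjusted p 0.0179), pathogenesis-related (-0.12, adjusted p 0.0219), abscisic acid (-0.09, adjusted p 0.0297), protease inhibitor (-0.25, adjusted p 0.0297) and glutathione S-transferase genes (-0.22, adjusted p 0.0483), the last with a median of 0.09 under between-array scaling, where the direction turned. Photosynthesis (0.14, adjusted p 8.98e-08), ribosomal protein (0.13, adjusted p 3.53e-07) and common symbiosis genes (0.14, adjusted p 8.67e-05) were higher. No member of these 12 lists passed (0 in limma). Of 105 mycorrhiza marker probes 3 rose and 0 fell (5 and 1 adjusted over the list alone), with no shift of the list (adjusted p 0.608).

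Jasmonate, isoflavonoid, common symbiosis and photosynthesis held without each replicate in turn, but scaling between arrays ended the isoflavonoid call (median -0.03 in place of -0.33, adjusted p 0.474). It also ended those of phenylpropanoid (0.148), pathogenesis-related (0.343), and protease inhibitor, abscisic acid and glutathione S-transferase genes (0.566 each). Agilent's processed signals and log ratios ended phenylpropanoid (0.19 and 0.207), peroxidase (0.127 and 0.108), protease inhibitor (0.842 and 0.671), glutathione S-transferase (0.167 and 0.207) and abscisic acid genes (0.2 and 0.33), and the processed signals pathogenesis-related genes (0.0722). The other 8 calls ended without mycorrhizal pathogen replicate 1, whose values carried adjusted p to 0.123 for phenylpropanoid, 0.477 for pathogenesis-related, 0.288 for protease inhibitor, 0.0686 for peroxidase, 0.152 for glutathione S-transferase, 0.92 for cell wall (where the direction turned), 0.599 for ribosomal and 0.347 for abscisic acid genes. Without pathogen replicate 1 the calls of pathogenesis-related (0.0661), protease inhibitor (0.453) and abscisic acid genes (0.211) ended, and without pathogen replicate 3 that of the cell wall (0.157). Without mycorrhizal pathogen replicate 2 protease inhibitors reached 0.0771, and without replicate 3 the cell wall list 0.0614. The glutathione S-transferase call also ended without control replicate 1 (0.0617) or 2 (0.0551), pathogen replicate 2 (0.0938) or 3 (0.089), mycorrhizal replicate 2 (0.0692) or mycorrhizal pathogen replicate 2 (0.138). On slides 1 and 2 the medians differed in sign for photosynthesis (-0.19 and 0.43), ribosomal proteins (0.50 and -0.24), cell wall (-0.24 and 0.10) and pathogenesis-related genes (-0.34 and 0.00523). The slide block ended the cell wall call (adjusted p 0.225; over all alternatives 1.75e-06 to 0.92) and made salicylate signalling a call (median -0.25, adjusted p 0.0252; 0.0433 with the replicate block, and 0.0252 to 0.379 over all alternatives). Calls also began for salicylate signalling without mycorrhizal pathogen replicate 3 (0.0395), resistance genes and receptor-like kinases without replicate 2 (0.0467), and nitrate and water transport without replicate 1 (0.00365). The refitted background ended the calls of protease inhibitors (0.0908), glutathione S-transferases (0.149) and abscisic acid (0.0598). The protease inhibitor call ended in 12 alternatives, with medians of -0.02 with no filter (0.496) and -0.03 with array weights (0.86), and ran from 0.00384 to 0.953. That of abscisic acid ended in 12 as well and ran from 0.0154 to 0.885, and that of pathogenesis-related genes ended in 8 and ran from 0.00229 to 0.885. The number of probes was 3 without pathogen replicate 2, 12 without pathogen replicate 3, 17 without mycorrhizal pathogen replicate 2, 5 with the slide block, 28 with the refitted background and 0 with between-array scaling or with limma's trend and robust options, against 2778 at an unadjusted p under 0.05 in the planned limma fit.

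**Figure D2:**
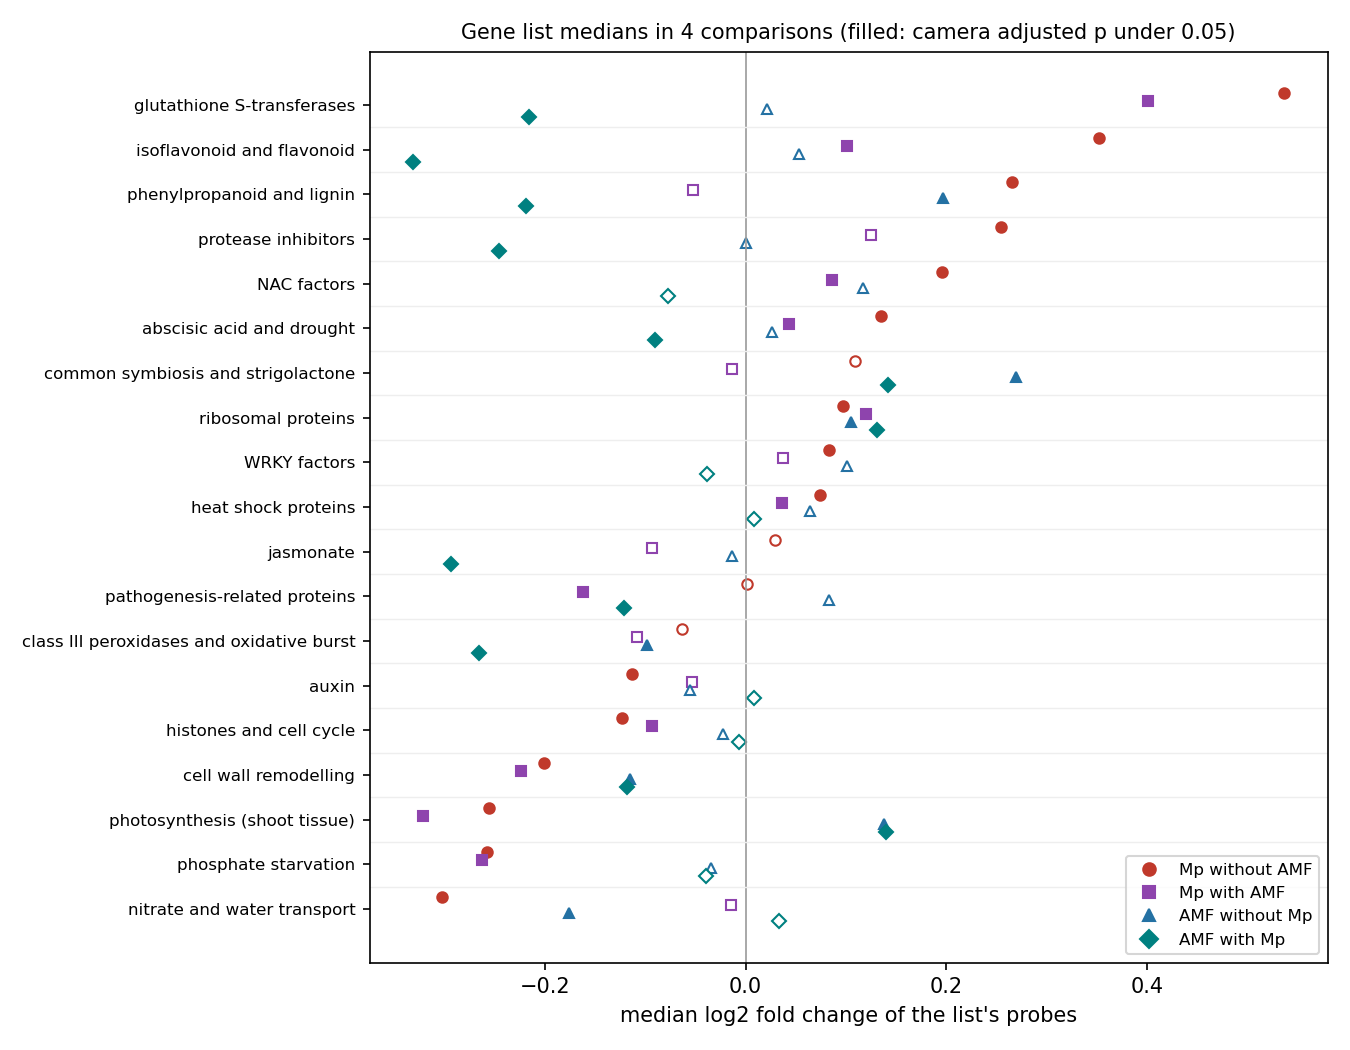
Median log2 fold change of each gene list (x axis) in the 4 comparisons between pairs of groups, with 1 line per list. Filled points have a camera adjusted p under 0.05 with the preset correlation. The glutathione S-transferase list lies at 0.54 and 0.40 for the pathogen without and with mycorrhiza, and the isoflavonoid list at 0.35 and 0.10.

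Whether the pathogen response depended on mycorrhiza was tested as the difference between the 2 pathogen effects. All 6 probes that passed had a lower pathogen effect in mycorrhizal roots. The GH3 probe BU547810 differed by -3.29 ± 0.38 (adjusted p 0.0282), with group means of 0.12 in control, 2.17 in pathogen, 3.78 in mycorrhizal and 2.54 in mycorrhizal pathogen roots. Beta-1,3-glucanase (BU549819) differed by -2.96 ± 0.36 (adjusted p 0.0322), from means of -0.09, 2.68, 1.10 and 0.91 in the same order. Anthocyanin 5-aromatic acyltransferase (BM094527) differed by -2.50 ± 0.27 and the auxin response element-like sequence BU547804 by -2.45 ± 0.25 (adjusted p 0.0231 each). Carbonic anhydrase differed by -2.41 ± 0.30 (adjusted p 0.0398) and had means of 0.02, 0.01, 2.91 and 0.49. The remaining probe, BU550330, has no gene name and is given outside the rule for named genes, chosen after its value was seen, at -1.41 ± 0.19 (adjusted p 0.048). Over the alternatives the adjusted p of the 5 named probes ran from 0.000904 to 0.989. None of the 5 passed without control replicate 1 (0.109 to 0.172), 2 (0.0729 to 0.105) or 3 (0.112 to 0.194), or without mycorrhizal replicate 1 (0.0672 to 0.0877). Some were lost without pathogen replicate 1 (up to 0.0825), 2 (up to 0.218) or 3 (up to 0.0947), mycorrhizal replicate 2 (up to 0.0541), or mycorrhizal pathogen replicate 1 (up to 0.0983) or 2 (up to 0.0739).

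Among lists, phenylpropanoid genes had a median interaction of -0.39 (adjusted p 2.27e-07; 0 rises and 2 falls adjusted over the list alone) and isoflavonoid genes of -0.43 (adjusted p 5.54e-06; 0 and 3). Pathogenesis-related genes had -0.11 (adjusted p 0.0135, 1 fall; 0 and 5 adjusted over the list alone) and jasmonate genes -0.19 (adjusted p 0.0299). Nitrate and water transport genes had 0.23 (adjusted p 0.00045), the median being -0.30 without mycorrhiza and -0.01 with it. With Agilent's processed signals and log ratios their interaction was -0.29 and -0.31, against -0.29 and -0.45 over all probes, and did not pass. Without mycorrhizal pathogen replicate 1 the pathogenesis-related call ended (0.183). The jasmonate call ended without that replicate (0.0915), without control replicate 1 (0.114), pathogen replicate 1 (0.163), mycorrhizal replicate 1 (0.236) or 3 (0.0584) or mycorrhizal pathogen replicate 3 (0.172), and with the refitted background (0.0574), in 14 alternatives in all, with a range of 0.000562 to 0.719. The phenylpropanoid, isoflavonoid and nitrate calls held without each replicate. Scaling between arrays ended the isoflavonoid (0.229), jasmonate (0.229), nitrate (0.14) and pathogenesis-related calls (0.385). Agilent's processed signals and log ratios ended isoflavonoid (0.201 and 0.448), pathogenesis-related (0.201 and 0.204), jasmonate (0.493 and 0.719) and nitrate and water transport genes (0.692 and 0.719), and the log ratios phenylpropanoids (0.0578). Leaving out a replicate also made calls of 11 other lists, most often protease inhibitors (8 of 12 replicates, adjusted p 0.00662 to 0.0463) and auxin (5 of 12, 0.013 to 0.0427). With slide as a block the 5 calls held, and protease inhibitors (-0.38, adjusted p 0.00253), glutathione S-transferases (-0.32, 0.00253), cell wall (0.09, 0.00846) and histones (0.06, 0.0042) were added. Over all alternatives the adjusted p of these 4 ran up to 0.870, 0.913, 0.933 and 0.983. The slide block also used single arrays and another form of camera, so these 4 cannot be put down to the slide alone. With an estimated correlation no list passed (0 by camera, smallest adjusted p 0.464), and fry called 0.

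The 6 probes (0 higher, 6 lower in limma) compare with 2179 at an unadjusted p under 0.05. The count was 0 without any of control replicates 1, 2 and 3 or mycorrhizal replicate 1, 2 without pathogen replicate 1, 1 without pathogen replicate 2, and 4 without pathogen replicate 3 or mycorrhizal replicate 2. It was 10 without mycorrhizal replicate 3, 2 without mycorrhizal pathogen replicate 1 or 2, and 29 without replicate 3. The slide block gave 2 and the refitted background 0. On the refitted background the 6 values had a median of -2.30 against -2.48, while their median SE rose to 0.37 from 0.288.

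Averaged over mycorrhizal status, the pathogen raised 12-oxophytodienoate reductase by 6.34 ± 0.37 (adjusted p 2.62e-06), GST 7 by 5.91, CPRD2 by 5.53 and GST 10 by 5.29. The 13 list calls of this effect were lost with an estimated correlation (0 by camera, smallest adjusted p 0.342), while fry called 9. Photosynthesis genes had 1 rise and 38 falls among 185, or 1 and 69 adjusted over the list alone (median -0.28, adjusted p 5.26e-13). Cell wall genes showed 6 rises and 26 falls, with 6 and 39 adjusted over the list alone (median -0.17, adjusted p 1.46e-05). Of phosphate starvation genes 2 rose and 11 fell (3 and 16 adjusted over the list alone; median -0.25, adjusted p 6.03e-05, but -0.02 and 0.135 with Agilent's processed signals). Glutathione S-transferases had 23 rises and 1 fall (median 0.48, adjusted p 8.01e-10). A plasma membrane intrinsic polypeptide (BW663363) fell by 2.32, vacuolar processing enzyme VPE2 (BW662139) by 2.03 and a wound-induced protein (CF922282) by 1.95. In limma 3498 probes passed, 1864 higher and 1634 lower, but 1052 and 2823 with median centring and 432 and 46 with Agilent's processed signals, so the majority direction depends on the scaling. The count was 2323 and 2081 without control replicates 2 and 3, 2054 and 2280 without mycorrhizal replicates 1 and 2, 3090 with the slide block and 5389 with the refitted background. The WRKY call (adjusted p 0.043) ended without control replicate 1 (0.122), pathogen replicate 3 (0.0608), mycorrhizal replicate 2 (0.0869) or mycorrhizal pathogen replicate 3 (0.0523), in 13 alternatives in all with a highest of 0.138, and the phenylpropanoid call (adjusted p 0.0131) without the last of these (0.0712). The slide block ended the WRKY call (0.109) and made nitrate and water transport a call (median -0.17, adjusted p 0.0124; over all alternatives 0.00615 to 0.137). Leaving out a replicate made calls of nitrate and water transport (3 of 12, 0.00615 to 0.0397), protease inhibitors (5 of 12, 0.00346 to 0.0403) and peroxidases (without mycorrhizal pathogen replicate 2, 0.031).

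Averaged over pathogen status, mycorrhiza raised the serine carboxypeptidase BE657431 by 6.67 ± 0.25 (adjusted p 1.37e-06), the cucumisin-type protease by 3.63 and ZOG1 by 2.74. CX711554 rose by 3.50, CO985404 by 2.59 and the reversibly glycosylated polypeptide by 2.51. The 6 list calls of this effect were lost with an estimated correlation (0 by camera, smallest adjusted p 0.515) and in fry (0). The common symbiosis and strigolactone list was higher, with 1 rise and 0 falls, 9 and 0 adjusted over the list alone, and a median of 0.21 (adjusted p 1.18e-07). Photosynthesis (median 0.14, adjusted p 2.59e-10) and ribosomal protein genes (0.13, adjusted p 5.9e-08, but 0.06 and 0.0602 with median centring) were higher too. Jasmonate (-0.17, adjusted p 9.18e-05; 0 rises and 5 falls adjusted over the list alone), cell wall (-0.11, adjusted p 0.000364) and class III peroxidase genes (-0.16, adjusted p 2.96e-05) were lower, the last with a median of 0.04 with Agilent's processed signals (adjusted p 0.137). The cell wall call ended without mycorrhizal replicate 3 (0.11) or mycorrhizal pathogen replicate 1 (0.0935). Without mycorrhizal replicate 3 isoflavonoids (median -0.14, adjusted p 0.00028), glutathione S-transferases (-0.20, 0.000714) and protease inhibitors (-0.17, 0.0343) became calls, and with the slide block the mycorrhiza markers (0.02, 0.000521; over all alternatives to 0.640). In limma 209 probes passed, 164 higher and 45 lower (702 and 640 with array weights). The count was 108, 95 and 91 without control replicates 1, 2 and 3, 94 and 134 without pathogen replicates 2 and 3, and 109, 107 and 388 without mycorrhizal replicates 1, 2 and 3. It was 811 and 117 without mycorrhizal pathogen replicates 2 and 3, 216 with the slide block and 555 with the refitted background.

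**Figure D3:**
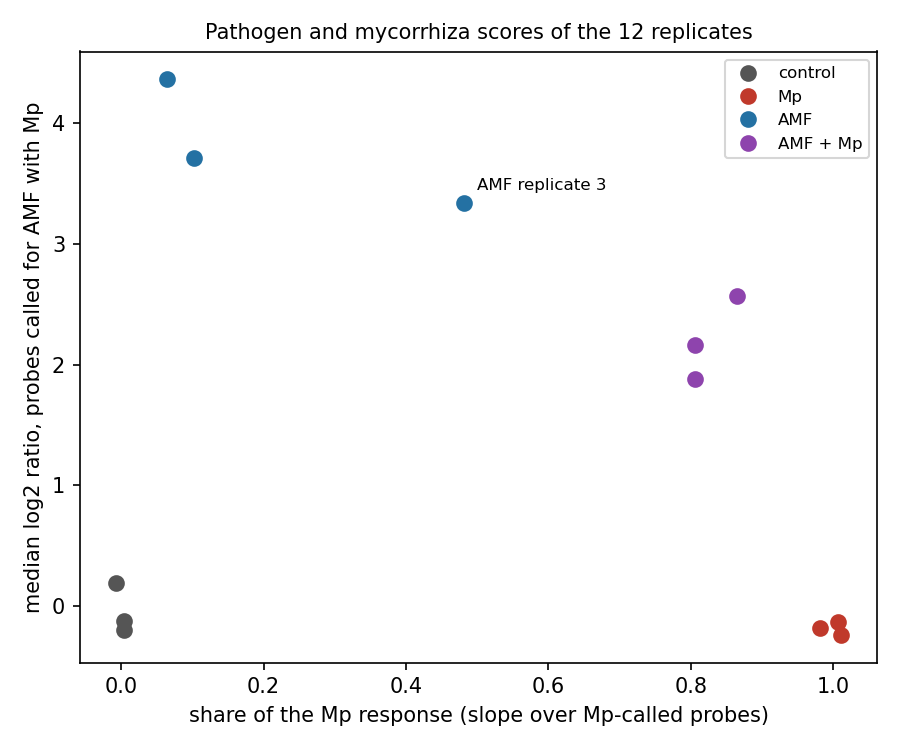
Each of the 12 replicates by its share of the pathogen response (x axis, 0 at the control mean and 1 at the pathogen mean, on probes called for the pathogen with the refitted background) and by the median log2 ratio of the 7 probes raised by mycorrhiza under the pathogen (y axis). Mycorrhizal replicate 3, marked, has a share of 0.482, against 0.102 and 0.0652 for the other mycorrhizal replicates.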

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

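The tests of mycorrhizal replicate 3, of the refitted background and of the estimated correlation in this part were chosen only after the result was seen, and the counts over other groupings of the samples were planned. What marked the results here is a test of the difference between the pathogen effect with and without mycorrhiza. It passed for 6 probes: the auxin response element-like BU547804 (-2.45), beta-1,3-glucanase BU549819 (-2.96), carbonic anhydrase BW660123 (-2.41), anthocyanin 5-aromatic acyltransferase BM094527 (-2.50), the unnamed BU550330 (-1.41) and GH3 BU547810 (-3.29), all on the log2 scale. It also passed for 5 gene lists, with medians of -0.387 for phenylpropanoid, -0.426 for isoflavonoid, -0.110 for pathogenesis-related, -0.193 for jasmonate and 0.227 for nitrate and water transport genes. The last had -0.289 and -0.312 with Agilent's processed signals and log ratios, where the median of all probes was -0.291 and -0.446. None of the 5 passed with an estimated correlation (0 by camera, smallest adjusted p 0.464) or in fry (0). With slide as a block, and the preset correlation, these 5 lists passed too, and 4 more did: protease inhibitors (-0.376), glutathione S-transferases (-0.316), cell wall (0.0929) and histones (0.0622). That fit also used single arrays and tested lists on t statistics, so the 4 cannot be put down to the slide alone.

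For the 6 probes, the background fit on 2 arrays was weighed. With that fit corrected the interactions kept 0.930 of their median size, -2.30 against -2.48, but the median SE went from 0.288 to 0.370 and 0 of the 6 passed in limma, where adjusted p were 0.105 to 0.287 (over all alternatives of the 5 named probes 0.000904 to 0.989). With refitted sizes over planned SEs 3 of the 6 probes reached the smallest t of the planned calls (7.64), with planned sizes over refitted SEs 1 did, and with both refitted 0. With the 6 chosen by planned t, this cannot apportion the loss. Most of the size was kept and the calls were not, so the effect of the background fit on these 6 calls and a real interaction cannot be told apart here. Groupings of the 12 samples other than the real one also bear on the count. Of 100 groupings 5 gave at least 6 probes, and the highest other count was 755, so chance is not excluded. That grouping set slides 2 and 3 (pathogen replicates 2 and 3, mycorrhizal pathogen replicate 2) against slides 1 and 5, and it put both arrays with a misfitted background on the same side. With the refit the same grouping gave 346 and the real one 0 (2179 at an unadjusted p under 0.05 in the planned limma fit). Exchanging labels within a single pathogen stratum turns the mycorrhizal effect into an interaction, which also raises counts, and this grouping did so for the roots without the pathogen. A structure of the samples by slide was not separated from that. With slide as a block the real count was 2.

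For the phenylpropanoid, isoflavonoid and pathogenesis-related lists, lower in the interaction, 3 explanations were weighed. Without mycorrhizal replicate 3 the largest adjusted p of the 3 lists was 0.0375, which argues against that replicate alone as the source, though the isoflavonoid median went to -0.25 from -0.43. With the background refitted the largest was 0.0109, which argues against the background fit. What stays open is that members of a list vary together. With an estimated correlation (0.078, 0.104 and 0.049) the smallest adjusted p was 0.464, so correlated members could account for these calls. Over the alternatives other than that one, the adjusted p ran from 7.76e-10 to 0.0578 for phenylpropanoid, 8.32e-09 to 0.448 for isoflavonoid and 0.00026 to 0.444 for pathogenesis-related genes. Without mycorrhizal pathogen replicate 1 the last of these had 0.183. Over all comparisons 69 list calls were made, and 7 of 100 groupings gave at least as many, the highest being 76, so chance is not excluded for that number. A weaker pathogen response in mycorrhizal roots, which the groups of this design name, stays among the open explanations and was not tested apart from the interaction itself.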

How the results depend on the processing

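The refitted background, the fit without slide 1, the refit without mycorrhizal replicate 3 and the fit with outlier spots kept were chosen only after the result was seen, and the other alternatives were planned. Counts below are probes past the threshold, in the order pathogen effect without mycorrhiza, pathogen effect with mycorrhiza, mycorrhizal effect without the pathogen, mycorrhizal effect with the pathogen, interaction, average pathogen effect and average mycorrhizal effect. The planned fit gave 2391, 397, 181, 7, 6, 3498 and 209. Aquantile gave the same numbers, since it leaves log ratios as they are. Keeping outlier spots or using either technical array alone kept every count within 1.5 times.

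Agilent's processed signals gave 271, 33, 35, 1, 478 and 37 for all but the mycorrhizal effect with the pathogen, and 43 list calls in place of 69. Agilent's log ratios gave 234, 36, 42, 1, 434 and 49 for the same comparisons, and 42 list calls. No background subtraction gave 3632, 768, 288, 31, 0, 5474 and 561. The refitted background gave 3600, 751, 311, 28, 0, 5389 and 555, and together with leaving out mycorrhizal replicate 3 it gave 3882, 1803, 512, 93, 1, 5961 and 824. Array weights, which gave control replicate 3 and pathogen replicate 3 weights of 7.18 and 7.98, passed 12407 probes for the pathogen, 2067 for mycorrhiza, 40 for the interaction and 1342 for average mycorrhiza. Without slide 1, and so with 2 replicates in 3 groups, the counts were 896, 213, 81, 3, 1, 1704 and 92, a fit on fewer samples. Scaling between arrays gave 364 and 44 for the pathogen without and with mycorrhiza, 0 for mycorrhiza with the pathogen and 1326 for the average pathogen effect. Median centring gave 114 for mycorrhiza, 3 with the pathogen, 0 for the interaction and 123 for average mycorrhiza. Cy5 alone gave 113, 20 and 0 for the first 3 of these. A filter on both channels gave 87 for mycorrhiza and 3 for the interaction. The interaction was 0 with no filter, and limma's trend and robust options gave 0 for it and for mycorrhiza with the pathogen. Beside these counts of 0 stand 2179 and 2778 at an unadjusted p under 0.05 in the planned limma fit. A minimum of 2-fold left 1299 for the pathogen, 991 for its average and 93 for average mycorrhiza. Fitting only the groups compared gave 62 for the pathogen with mycorrhiza. The slide block gave 254 for it and 2 for the interaction. The replicate block gave 1926, 303, 125, 5, 0, 3107 and 114. With group means subtracted, replicates with the same number correlated at 0.22, 0.16 and 0.09 between control and pathogen roots, which shared slides 1, 2 and 3. In the other comparisons the values were -0.36 to 0.16. There, same-number replicates with a common slide had 0.11, 0.06, 0.16 and -0.09, and those on different slides -0.36 to -0.14. Pairing by number thus largely followed the slide and was not tested apart from it. Except where the construction is named, the cause was not tested.

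Leaving out each replicate in turn gave 1016 to 3124, 165 to 1010, 82 to 317, 3 to 17, 0 to 29, 2054 to 5021 and 91 to 811 probes, and 61 to 77 list calls. The low ends came without control replicate 3, mycorrhizal replicate 1, control replicate 3, pathogen replicate 2, each control replicate or mycorrhizal replicate 1, mycorrhizal replicate 1 and control replicate 3. The high ends came without mycorrhizal pathogen replicate 1, mycorrhizal replicate 3, mycorrhizal pathogen replicates 2, 2 and 3, and replicate 2 for both averages. No group was left with 1 sample.

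The share of rises also moved. Of the pathogen calls 65.0% were higher, against 94.8% with Agilent's processed signals, 97.4% with its log ratios and 40.8% with median centring. In mycorrhizal roots the share was 61.5%, against 97.0%, 91.7% and 32.9%, and 15.9% with scaling between arrays. For the average pathogen effect it was 53.3%, against 90.4%, 89.6% and 27.1%. For mycorrhiza it was 91.2%, but 51.5% with array weights, and 78.5% and 52.3% for its average. Over all probes the median pathogen effect was 0.20 and 0.30 with Agilent's signals and log ratios, and the median interaction -0.29 and -0.45, against 0.00159 and -0.0269 in the planned fit. The cause was not tested.

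Camera with an estimated correlation called 0 lists and fry called 17. Of the 69 list results called in the planned fit, camera's direction turned in 3. Glutathione S-transferases for mycorrhiza with the pathogen had a median of 0.0927 under scaling between arrays, and ribosomal proteins -0.0686 without slide 1. For the cell wall list in the same comparison camera's direction turned without mycorrhizal pathogen replicate 1, where the median was -0.0294, and it ranged from -0.240 to -0.0294 over the replicates left out. Among lists not called in the planned fit, 2 passed with the opposite direction by camera, which can differ from the sign of the median. These were glutathione S-transferases for mycorrhiza without mycorrhizal replicate 3 (-0.126, and -0.127 with the refit, against 0.021) and ribosomal proteins in the interaction without mycorrhizal pathogen replicate 1 (-0.0993) or slide 1 (-0.193), against 0.0291. The median itself, not set against other genes, changed sign for 18 of the 69 called list results, in 30 cases: 7 each with Agilent's processed signals, its log ratios and median centring, 3 each without slide 1 and without mycorrhizal pathogen replicate 1, 2 with Cy5 alone and 1 with scaling between arrays. Without that replicate these were heat shock (-0.0131) and ribosomal proteins (-0.00934) for the pathogen in mycorrhizal roots and ribosomal proteins for mycorrhiza with the pathogen (-0.0222). The largest change of sign was that of nitrate and water transport in the interaction, to -0.312 from 0.227 with Agilent's log ratios. There the median of all probes was -0.446, so the list still lay above that median. Agilent's signals and median centring move the median of all probes, while camera compares a list with other genes. A changed sign there is thus not in itself a reversal against other genes. The cause of the changes was otherwise not tested.

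Of 210 named-gene results 200 kept their call with the refitted background, 183 with the slide block, 176 with the replicate block, 159 with median centring, 41 with scaling between arrays, 46 with Agilent's processed signals and 44 with its log ratios. In the values the authors deposited per group, 136 lay within 1 SD and 0 changed sign, a comparison without a test. Signs turned with Agilent's signals alone, and no value that turned passed there. The values given are with the processed signals and then with the log ratios. For the pathogen without mycorrhiza these were glycerol-3-phosphate acyltransferase (-0.712 and -0.547), peroxidase sEPa1 (0.487 processed), WRKY4 (-0.611 and -0.360), a Myb factor (0.962 and 1.25), photosystem subunit PsaK (0.966 and 1.21), a cyclin (0.452 and 0.640) and an aquaporin (0.173 and 0.310). With mycorrhiza it was peroxidase pxdD (0.630 and 0.600). For mycorrhiza they were sEPa1 (1.08 and 0.455), a protein kinase (0.165 and 0.480) and GST 9 (-0.0528 processed). For the average pathogen effect they were Eds5 (0.550 and 0.652), serine carboxypeptidase CO985404 (0.195 and 0.203), sEPa1 (0.0562 processed), the Myb factor (0.203 and 0.313), histone H3.3 (1.19 and 0.786) and alpha-tubulin 2 (1.01 and 0.458). For average mycorrhiza they were ornithine decarboxylase (0.186 processed) and lipoxygenase L-5 (0.0763 log ratio). The cause was not tested. Signal over background limits what slide 1 can show, with medians of 69.1 to 92.8 against 196.6 to 475.6 on the other slides.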

Other observations

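In this part the test of a swap was chosen only after the result was seen, and the tests of the slide and of a mixture, like the counts of other groupings, were written before it. Mycorrhizal replicate 3 lay toward the pathogen groups. On the 3600 probes called for the pathogen with the refitted background, where the control mean is 0 and the pathogen mean 1 by construction, its share of the pathogen response was 0.482, against 0.102 and 0.0652 in mycorrhizal replicates 1 and 2 and 0.806, 0.865 and 0.806 in the mycorrhizal pathogen replicates. Its 2 technical arrays had 0.486 and 0.478. A swap with a mycorrhizal pathogen replicate needs a partner out of place there, but the lowest of those shares was 0.806, above the other mycorrhizal replicates by 0.704 with an SD of 0.034, which argues against a swap. In the planned fit the lowest share was 0.653, in mycorrhizal pathogen replicate 2. That too lay above the 0.0933 and 0.0456 of mycorrhizal replicates 1 and 2. A slide effect is argued against too. The control array on the same slide differed by 0.0243 from the other array of the same RNA, against an excess of 0.403 in the mycorrhizal array.

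A mixture with RNA of inoculated mycorrhizal roots stays open. The share fitted on 2257 rising probes was 0.355, and over 1325 falling probes the measured median was -0.07 against -0.13 predicted, a difference of 0.0583 that lies within 2 times the 0.0514 between mycorrhizal replicates 1 and 2. Such a mixture, or pathogen or another stress reaching that pool, could raise the same genes, and the design gives no group that would test the latter. The replicate was kept, since its source stays open. Leaving it out gave 1010 probes for the pathogen in mycorrhizal roots against 397.

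Other groupings of the samples were fitted for each comparison. With 3 replicates against 3 there are 10 groupings, too few for a share under 0.05. The real grouping gave 2391 probes for the pathogen and the highest other 0 (1 of 10 as large). For the pathogen in mycorrhizal roots these were 397 and 149 (1 of 10), the latter with mycorrhizal replicate 3 and mycorrhizal pathogen replicate 2 exchanged. For mycorrhiza they were 181 and 0 (1 of 10), and 7 and 0 with the pathogen (1 of 10). For the average pathogen effect 2 of 100 groupings gave at least 3498 probes, a share under 0.05. The highest other was 3632, with the same 2 replicates exchanged. With the refitted background the real count was 5389 and the highest other 2540. For the average mycorrhizal effect 2 of 100 gave at least 209, also a share under 0.05 and, like the former, not adjusted over the comparisons. The highest other, 755, set slides 2 and 3 against slides 1 and 5 among the pathogen samples, and kept the control and mycorrhizal groups apart. It holds several times the real count, which points to a structure of the samples, so the share under 0.05 does not exclude chance. With slide as a block the real count was 216. With the refitted background it was 555, against 346 for the highest other. Beside each 0 in other groupings stands only limma's adjusted count, since no other tool was run on them.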
